A study of Mus musculus with 8 samples.

How the data were processed

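RNA was measured in gallbladders of female mice homozygous for the obese (ob) mutation of the leptin gene, which leaves them without functional leptin. Per the labels, 24 mice arrived at 7 weeks of age and had 1 week to acclimate. Recombinant mouse leptin (5 µg per g body weight, 12 mice) or saline (12 mice) was then injected into the peritoneum each day for 4 weeks. Gallbladders were removed at 12 weeks of age after an overnight fast, and total RNA was taken from pools of 3 gallbladders, giving 4 leptin pools and 4 saline pools. Each pool was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, a 1-colour array on which each probe set reports 1 transcript or a group of related transcripts. Pools are numbered as in the labels, saline 1 to 4 and leptin 5 to 8, so no number is shared between treatments and nothing was paired.

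The values deposited by the authors are intensities on a linear scale, 1 MAS 5.0 signal per probe set and array. MAS5 is named in the submitters' processing notes, and the series' design text names the array maker's software for the same step. Its version, the detection calls and scan dates are not given in the sources used here, so batches could not be looked for. Every array had a 2% trimmed mean signal of 250, which is the global scaling of that software. Such scaling fixes the trimmed average of an array, so a change shared alike by all transcripts would not be seen.

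From these values, each array was divided by its 2% trimmed mean and multiplied by the mean of these, which changed nearly nothing. Signals were taken to log2(signal + 8.2), where 8.2 is the 10th percentile of all values, so fold changes of dim genes are understated. The 64 control probe sets were left out, and 22519 of the 45101 probe sets, those at or above the median mean log2 value, were tested. No column of the table was left unused. Leptin was compared with saline by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Log2 fold changes are leptin minus saline, with their standard error (SE), and n = 4 pools in each treatment throughout.

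Probe sets were named from the array's annotation. Of these, 34958 had 1 gene symbol, 932 had several and 9211 had none in the table used here. Symbols of 34754 were updated through their Entrez identifiers to the mouse gene table of assembly GRCm38.p6, from which no coordinates were taken. A gene was represented by its brightest probe set with 1 symbol, which gave 11719 tested genes. Immunoglobulin probe sets belong to multigene families whose members can share probes, so the member named is uncertain. A probe set counted as not above background on an array when its signal lay under 46.0, the 95th percentile of the 27 control probe sets for bacterial sequences not added to the samples. Where at least 2 pools of a treatment lay under it, the fold is given as a lower bound, with those pools set at it.

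The 37 gene lists held 676 symbols, of which 615 were on the array under 1 symbol and 507 were tested; 2 were matched through an older name. Lists with at least 5 tested genes, 32 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list score of a pool is the mean over its genes of the log2 value minus the gene's mean over the 8 pools. Scores and array quality values were compared by two-sided exact permutation tests over the 70 assignments of 8 pools, which cannot go below p = 0.0286.

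The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said. The rule took the 12 largest rises and 12 largest falls, by fitted log2 fold change, among called genes whose 4 leptin pools all lay on 1 side of the 4 saline pools. It added the leptin signalling list and 15 gallbladder and cell type genes whatever they did, up to 4 members of each list past its threshold and up to 2 of every other list. Alternatives covered the scaling between arrays, the pseudocount, the filter on dim probe sets, the variance model, array weights, the threshold, the set test and leaving out each pool.

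The fit was tested on simulated data with the arrays' own spread. Of 200 probe sets changed 1.5-fold, 2-fold and 4-fold among 22519, it recovered 6%, 55% and 81%, with 7.69%, 2.65% and 2.99% false calls. It made 0 calls where nothing was changed. The set test found 10 of 10 lists shifted by 0.5 on the log2 scale and 0 others. Genes varied independently in the simulated data, so this does not test the preset correlation of 0.01. In the real lists the estimated correlation was, for example, 0.10 for cholesterol synthesis, 0.45 for proliferation and 0.79 for hepatocyte markers. On the real arrays the set test called 1 to 8 lists, with a median of 5, in each of the 18 splits that put 2 leptin and 2 saline pools on each side. The number of arrays limits the precision: the median SE of a log2 fold change was 0.19, and the smallest called change was 0.29. The p-values measure the spread between pools of 3 mice, not between single mice.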

Results

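Gallbladder RNA of leptin-deficient ob/ob mice was compared after 4 weeks of leptin or saline, to find genes whose level in this organ leptin alters. There were 4 pools of 3 gallbladders for each treatment, and each was measured on 1 array of 45101 probe sets. No 2 arrays were identical: the mean absolute log2 difference between any pair lay between 0.27 and 0.48. The first principal component of the tested probe sets held 36.5% of the variance and separated all leptin pools from all saline pools. On the second, with 16.4%, the leptin 7 pool lay at -49.1 and the other 7 pools between -12.6 and 23.7.

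Some general measures of the arrays also lay apart between treatments. Of the 9 compared, the trimmed mean signal was fixed near 250 by the scaling and could not lie apart, yet it counted in the adjustment. None of the 9 passed 0.05 after adjustment, but 0.0286 is the smallest p that this test allows. The result after adjustment therefore does not show that the arrays were alike. The added control sequences BioB and CreX did not lie apart (exact permutation p = 0.743 and 0.8). The median signal was 98.9 ± 5.74 (SD, n = 4) in leptin pools and 81.8 ± 4.18 (SD, n = 4) in saline pools (exact permutation p = 0.0286, adjusted 0.0857 over 9 measures). Probe sets above background made up 69.4% ± 1.10 and 64.9% ± 1.49 (exact permutation p = 0.0286, adjusted 0.0857). The actin 3' to 5' signal ratio, which rises as RNA degrades, was 1.89 ± 0.207 with leptin and 1.60 ± 0.0882 with saline (exact permutation p = 0.0571). The same ratio of GAPDH was 0.818 ± 0.0248 and 0.813 ± 0.0409 (exact permutation p = 0.857). Mean correlation with the arrays of the same treatment was 0.943 ± 0.00750 with leptin and 0.962 ± 0.00328 with saline (exact permutation p = 0.0286, adjusted 0.0857). Without leptin 7, the exact permutation p was 0.0571 for the probe sets above background and 0.0286 for the actin ratio.

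**Figure D1:**
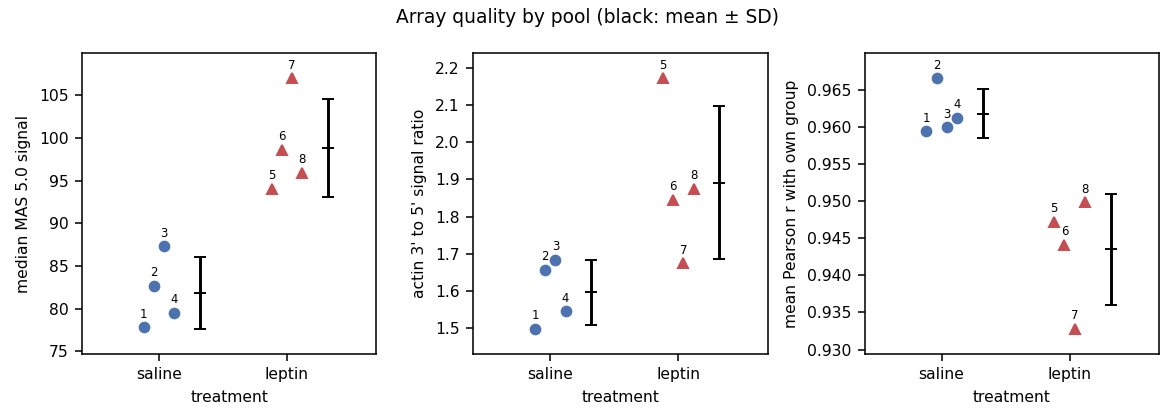
Median MAS 5.0 signal, actin 3' to 5' signal ratio and mean Pearson correlation with the arrays of the same treatment, for each pool (points, numbered) with mean ± SD of 4 pools. The vertical axes do not start at 0; all leptin pools lie above all saline pools in median signal, between 94.0 and 107.0 against 77.8 to 87.3.

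Genes of MHC class II presentation, of B and plasma cells and of the interferon response were higher with leptin, and genes of cholesterol synthesis were lower. These 4 lists passed with limma's camera at the preset and at an estimated correlation (adjusted p up to 0.0225 with the latter). Immunoglobulin M heavy chain (Ighm) rose by 6.76 ± 0.33 (SE) on the log2 scale, from a mean signal of 118 to 12250 (limma adjusted p = 8.2e-08), with 1 saline pool under background. Sult1e1, an oestrogen sulfotransferase, had a log2 fold change of -3.24 ± 0.26 (adjusted p = 1.2e-05). In all, 1561 of 22519 probe sets passed the threshold, 798 higher and 763 lower with leptin. Of the called probe sets, 140 had no single symbol. With each of 11719 genes read from its brightest probe set, 969 were called, 503 higher and 466 lower. Changes of at least 2-fold were found in 302 higher and 117 lower probe sets. The pools of the 2 treatments did not overlap in 15.5% of probe sets, against 2.86% by chance.

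With each array centred on its median, the split was 619 higher and 1322 lower. The count fell to 892, 943, 1028, 884 and 985 without saline 2, saline 4, leptin 5, leptin 6 and leptin 8. Without leptin 7 it was 1431. With the actin ratio as a covariate, a fit added after the data were seen, it was 654 (249 higher, 405 lower). The ratio itself differed between treatments, with means of 1.89 for leptin and 1.60 for saline. This fit therefore estimates the leptin effect less precisely, and a lost call alone does not show a smaller change. For some genes described below the log2 fold change itself was smaller with the covariate. It went from 0.86 to 0.40 for Socs2, from -0.96 to -0.46 for Krt7 and from 0.70 to 0.22 for Apoa1. For others that lost their call it was not smaller, such as Tff3 (0.79 and 0.86) and Creb3l1 (0.82 and 0.86).

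Jchain, the chain that joins IgM and IgA into polymers, rose by 5.77 ± 0.28 and Igkv8-30 by 5.64 ± 0.25, each with 1 saline pool under background. Igkv9-120 and Iglv1 lay under background in all 4 saline pools and were at least 30.9-fold and 23.0-fold higher with leptin (adjusted p = 2.6e-06 and 3.1e-06), and Igk rose by 3.12 ± 0.17. The chitinase-like gene Chil4, under background in 2 saline pools, was at least 73.9-fold higher (adjusted p = 2.6e-06), and Chil3 rose by 4.47 ± 0.39. Cxcl5, a chemokine that attracts neutrophils, lay under background in 3 saline pools and was at least 29.6-fold higher (adjusted p = 4.8e-05). Retnla, a marker of alternatively activated macrophages, rose by 3.29 ± 0.36. S100a8, a neutrophil calcium-binding protein, rose by 3.07 ± 0.20, and the iron-binding protein gene Ltf by 2.90 ± 0.29.

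Thrsp, a regulator of fat synthesis, changed by -2.44 ± 0.31, and the lipid droplet genes Cidea and Cidec by -2.41 ± 0.41 and -2.03 ± 0.26, with Cidea under background in 1 leptin pool. Fdps, of the cholesterol pathway, changed by -2.06 ± 0.21, and the desaturase gene Scd1 by -1.78 ± 0.13, from a mean signal of 13972 to 4067. The growth regulator gene Myc changed by -2.02 ± 0.17, and the replication genes Mcm5 and Mcm2 by -2.21 ± 0.25 and -1.89 ± 0.28. The acetyltransferase gene Nat8, under background in 2 leptin pools, was at least 5.63-fold lower (adjusted p = 0.0031). Tnfrsf12a changed by -2.14 ± 0.33 and the keratin gene Krt20 by -1.83 ± 0.30. With the actin covariate the calls of Nat8 (adjusted p = 0.0931), Tnfrsf12a (0.0931), Mcm2 (0.0521) and Krt20 (0.131) were lost.

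**Figure D2:**
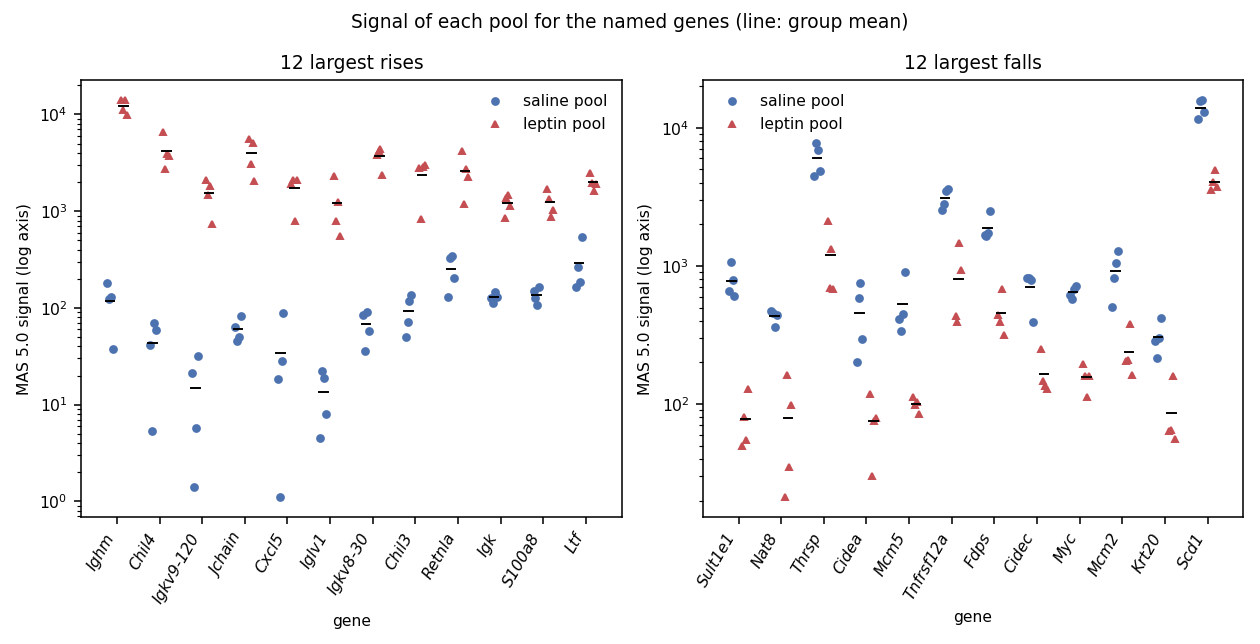
MAS 5.0 signal (log axis) of each saline pool (circles) and leptin pool (triangles) for the 12 genes with the largest fitted rises and the 12 with the largest fitted falls, with the group mean as a line. In each of them the 4 leptin pools lie entirely on 1 side of the 4 saline pools, as the rule for naming them required.

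Genes of antigen presentation rose as a group. All 7 tested genes of the MHC class II list rose, with a median of 1.98, and all 7 rose when adjusted over the list alone (camera adjusted p = 8.8e-15). The invariant chain gene Cd74 rose by 2.63 ± 0.11, H2-Eb1 by 2.20 ± 0.17, H2-Aa by 2.05 ± 0.099 and H2-DMa by 1.98 ± 0.21. Of 16 macrophage markers, 13 rose, also 13 adjusted over the list alone, and the median was 1.05 (camera adjusted p = 3.5e-15; adjusted p = 0.0510 with an estimated correlation). Examples were the signalling adaptor Tyrobp (1.89 ± 0.13), Laptm5 (1.82 ± 0.15) and Csf1r (1.09 ± 0.14), the receptor for macrophage growth factor.

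B and plasma cell markers and interferon-response genes also rose. In the B and plasma cell list 6 of 7 genes rose, also 6 adjusted over the list alone (median 1.47, camera adjusted p = 1.8e-10), among them the B cell gene Ms4a1 (1.36 ± 0.16) and the plasma cell gene Mzb1 (1.47 ± 0.18). In the interferon list 9 of 16 rose, and 14 adjusted over the list alone (median 0.75, camera adjusted p = 3.3e-10). Rtp4 rose by 1.41 ± 0.19 and the GTPase genes Iigp1 and Igtp by 1.42 ± 0.24 and 1.08 ± 0.20. The antiviral gene Ifit3, under background in 2 saline pools, was at least 4.22-fold higher (adjusted p = 0.0031). With the actin covariate the calls of Ifit3 (adjusted p = 0.0617), Iigp1 (0.154) and Igtp (0.138) were lost. The fitted log2 fold change of Ifit3 was 2.16 in that fit and 2.29 without the covariate. Those of Iigp1 and Igtp were 0.68 and 0.84 with it. The cholesterol synthesis, MHC class II, B and plasma cell and interferon lists were the 4 that also passed with an estimated correlation, with adjusted p of 0.0176, 0.0225, 0.0176 and 0.0176.

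Of 15 acute phase and inflammation genes, 8 rose, also 8 adjusted over the list alone together with 2 that fell there (median 0.41, camera adjusted p = 2.3e-05; adjusted p = 0.171 with an estimated correlation). Serum amyloid Saa3 rose by 2.68 ± 0.24, the siderophore-binding Lcn2 by 1.57 ± 0.20 and the interleukin 1 antagonist Il1rn by 1.57 ± 0.22. Of 6 mast cell markers, 3 rose, and 4 adjusted over the list alone (median 0.63, camera adjusted p = 0.0024; adjusted p = 0.0881 with an estimated correlation). They were Kit, Cpa3 and Cma1, at 0.82 ± 0.19, 0.66 ± 0.16 and 0.63 ± 0.18. Kit lost its call without saline 1, saline 2, saline 4, leptin 5, leptin 6 or leptin 8 (adjusted p up to 0.0628), Cpa3 without saline 1, saline 4 or any leptin pool (up to 0.0777), and Cma1 without any pool but leptin 6 (up to 0.110). All 3 calls were also lost under quantile and loess scaling (up to 0.108), without the filter (up to 0.0873) and with the actin covariate (up to 0.259). That of Cma1 was lost with median centring (0.0676), without the mean-variance trend (0.0606) and with array weights (0.0541) too. T and NK cell genes were mostly too dim: 3 were tested and 0 called, Klrd1 at 0.97 ± 0.34 (adjusted p = 0.107, under background in 1 saline pool) and Cd8a at 0.53 ± 0.23 (0.185), and 1 rose adjusted over the list alone. Klrd1 passed without leptin 8 (adjusted p = 0.0483).

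Genes of cholesterol synthesis, which liver also expresses, fell together in these pools. Of 20 tested, 14 fell and 0 rose, and 18 fell adjusted over the list alone; the median log2 fold change was -0.93 (camera adjusted p = 5.5e-18). Hmgcs1, an early enzyme of the pathway, changed by -1.31 ± 0.10, Sqle by -1.67 ± 0.17 and Cyp51 by -1.72 ± 0.19. Of 18 fatty acid and triglyceride synthesis genes, 6 fell, and 10 adjusted over the list alone (median -0.46, camera adjusted p = 1.6e-07; adjusted p = 0.0645 with an estimated correlation). Acly and Fasn, 2 enzymes of fatty acid synthesis, changed by -0.80 ± 0.11 and -1.17 ± 0.17. Fatty acid oxidation genes did not pass: 0 of 23 were called, and 0 adjusted over the list alone. Their median and mean were 0.035 and 0.032, while camera's direction was down (adjusted p = 0.949). The list's 2 lowest p-values were those of Acot2 (0.46 ± 0.14, adjusted p = 0.0615) and Angptl4 (-0.41 ± 0.14, 0.0956). Acot2 passed without leptin 5 (0.0352) and under quantile (0.0487) and loess scaling (0.0389) and among probe sets above the 75th percentile of brightness (0.0484), and Angptl4 without saline 1 (0.0142) and with array weights (0.0292). With the actin covariate the list passed, with a median of -0.38 (adjusted p = 0.0024).

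Adipocyte markers were lower as well, with 3 of 10 called and 6 adjusted over the list alone (median -0.57, camera adjusted p = 2.3e-05; adjusted p = 0.226 with an estimated correlation). Without saline 4 the median was -0.85. The called genes were Cidea, Cidec and the fatty acid transporter Cd36 (-0.49 ± 0.14), whose call was lost without any pool but saline 4 (adjusted p up to 0.131), under quantile and loess scaling (up to 0.130), and without the filter (0.0761) or the mean-variance trend (0.109). Pparg was at -0.58 ± 0.17 (adjusted p = 0.0593) and passed without saline 3 (0.0388), under quantile scaling (0.0438), with median centring (0.0278) and among probe sets above the 75th percentile of brightness (0.0468). Adipoq, an abundant adipocyte transcript, had a log2 fold change of -0.27 ± 0.51 (adjusted p = 0.793).

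Immediate early genes, which respond within minutes to stimuli and to handling, fell in 6 of 18 cases and in 11 adjusted over the list alone, where 1 rose (median -0.45, camera adjusted p = 1.6e-07; adjusted p = 0.0645 with an estimated correlation). Egr1 changed by -1.12 ± 0.14, Maff by -1.20 ± 0.17 and Klf6 by -1.01 ± 0.15. Of 13 proliferation genes, 7 fell, and 8 adjusted over the list alone (median -0.90, camera adjusted p = 1.2e-05; adjusted p = 0.233 with an estimated correlation). These 7 were the nucleotide synthesis gene Rrm2 (-1.74 ± 0.15) and 6 Mcm genes of the replication helicase, including Mcm6 (-1.42 ± 0.26). The mitotic genes Cdk1 and Top2a, named after their values were seen, were at 0.012 and -0.14 and not called. With the actin covariate the calls of Maff (-0.87, adjusted p = 0.0703) and Mcm6 (-1.46, 0.0712) were lost. The saline 4 pool scored 1.06 on this list, against 0.178 to 0.219 in the other saline pools, and without it the median was -0.60.

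Lists with smaller shifts fell too, and none of them passed with an estimated correlation. Circadian clock genes fell in 4 of 16 cases and 7 adjusted over the list alone (median -0.28, camera adjusted p = 0.0013; adjusted p = 0.121 with an estimated correlation), with Ciart, under background in 2 leptin pools, at least 3.41-fold lower. The list lost its call among probe sets above the 75th percentile of brightness (0.107), and Ciart with the actin covariate (0.0585). Glucocorticoid-responsive genes fell in 4 of 15 and 6 adjusted over the list alone (median -0.21, camera adjusted p = 0.0010; adjusted p = 0.233 with an estimated correlation), with Fkbp5 at -1.21 ± 0.17, Cdkn1a at -1.31 ± 0.23, Sgk1 at -0.75 ± 0.15 and Cebpd at -0.89 ± 0.17. The median was -0.10 without saline 2 and -0.33 without saline 4, and Cdkn1a (0.108) and Sgk1 (0.0823) lost their calls with the actin covariate. Glycolysis genes fell in 3 of 17 and 9 adjusted over the list alone (median -0.25, camera adjusted p = 0.0014; adjusted p = 0.121 with an estimated correlation), with Pdk1, a kinase that restrains pyruvate oxidation, at -0.62 ± 0.11. Of 31 oxidative phosphorylation genes, 3 fell, and 5 adjusted over the list alone (median -0.21, camera adjusted p = 2.2e-06; adjusted p = 0.306 with an estimated correlation), with Ndufa4 at -0.76 ± 0.098. Antioxidant genes fell in 3 of 18 and 4 adjusted over the list alone (median -0.19, camera adjusted p = 0.0081; adjusted p = 0.171 with an estimated correlation), with the metallothionein Mt2 at -0.62 ± 0.11 and Gclc at -0.71 ± 0.14. The antioxidant list lost its call under quantile (adjusted p = 0.0707) and loess scaling (0.179) and among probe sets above the 75th percentile of brightness (0.102), Gclc with the actin covariate (0.254), and the oxidative phosphorylation list under loess (0.141). Other called genes of these lists held less often. Cry1 (-0.98 ± 0.21) lost its call without saline 2 or leptin 6 (adjusted p up to 0.0524), Per2 (-0.80 ± 0.20) without saline 1, saline 2, saline 4, leptin 6 or leptin 8 (up to 0.0950), and Cry2 (-1.08 ± 0.30) without any pool but leptin 8 (up to 0.120). Ndufv2 (-0.37 ± 0.086) lost it without saline 2, saline 4, leptin 5, leptin 6 or leptin 8 (up to 0.0780), and Tkt (-0.37 ± 0.095) without any pool but saline 3 (up to 0.0953). Sdhb (-0.37 ± 0.099), Pgam1 (-0.41 ± 0.11) and Mt1 (-0.40 ± 0.11) lost it without any pool but saline 1 (up to 0.115, 0.101 and 0.120). Under quantile and loess scaling Ndufv2, Sdhb, Tkt and Pgam1 lost their calls (up to 0.130, 0.152, 0.261 and 0.123), as did Cry2 under quantile (0.0521) and Mt1 under loess (0.190). Without the filter or the mean-variance trend all of these but Cry1 lost theirs (up to 0.163), and Cry2 also with a pseudocount of 1 (0.0512), the robust variance model (0.0632) and array weights (0.0553). With the actin covariate none of these 8 was called (adjusted p from 0.0582 to 0.447). In that fit Cry1, Per2, Cry2 and Ndufv2 were at -0.63, -0.66, -1.08 and -0.34. Tkt, Sdhb, Pgam1 and Mt1 were at -0.19, -0.52, -0.58 and -0.40.

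Of 16 leptin signalling genes tested, 2 were called, and 3 adjusted over the list alone (median 0.12). The list did not pass with camera, which compares it with the other genes (adjusted p = 0.223), but passed with fry, which tests the list by itself (adjusted p = 0.0122). Socs2 and Cish, feedback inhibitors induced by STAT proteins, rose by 0.86 ± 0.20 and 0.75 ± 0.18 (adjusted p = 0.0222 and 0.0259). The Socs2 call was lost without saline 1, saline 2, leptin 5 or leptin 6 (adjusted p up to 0.0710) and under quantile and loess scaling (up to 0.0695). That of Cish was lost without saline 2, leptin 5, leptin 6 or leptin 8 (up to 0.0801), and both were lost with the actin covariate (0.438 and 0.228). Lep, the gene mutated in these mice, lay under background in 1 leptin pool. It was at -1.94 ± 0.57 (adjusted p = 0.0605) and passed without saline 4, at -2.55 (adjusted p = 0.0092), and under quantile (0.0425) and loess scaling (0.0446) and median centring (0.0428) and with array weights (0.0222). The leptin receptor gene Lepr was at 0.38 ± 0.20, Stat3 at -0.24 ± 0.14 and Socs3 at -0.10 ± 0.29, and 1 other probe set of Lepr was called higher. Jak2, Stat5a, Stat5b, Irs1, Ptpn1, Ptpn11, Leprot, Leprotl1, Grb2 and Sh2b1 were not called, with log2 fold changes from -0.37 to 0.53. Irs1 passed without saline 3 (adjusted p = 0.0462), and Ptpn11 without leptin 7 (0.0351) and with median centring (0.0478). Socs1 and Irs2 were too dim to be tested.

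Of genes for gallbladder contraction, Cckar, the cholecystokinin receptor that triggers emptying, rose by 0.93 ± 0.11 (adjusted p = 0.00022), from a mean signal of 625 ± 40.5 to 1196 ± 41.9 (SD, n = 4). It was the 1 gene of 11 called in the motility list, also 1 adjusted over the list alone (camera adjusted p = 0.159), where Gucy1a1 was at 0.48 ± 0.17 and its 1 other probe set was called higher. With fry the motility list passed (adjusted p = 0.0116). The smooth muscle list had 1 gene higher and 1 lower of 19, and 1 higher and 3 lower adjusted over the list alone (median -0.15, camera adjusted p = 0.0401; adjusted p = 0.671 with an estimated correlation). That list's call was lost without saline 2, saline 3, leptin 5, leptin 6 or leptin 8 (adjusted p up to 0.220), under quantile (0.367) and loess scaling (0.661), without the mean-variance trend (0.0631), among probe sets above the 75th percentile of brightness (0.150), with fry (0.453) and with the actin covariate (0.135). Its median was -0.25 without saline 1 and -0.24 without leptin 7. Smtn, a contractile-cell protein gene, rose by 0.65 ± 0.14, and the enteric actin gene Actg2 fell, with a log2 fold change of -0.58 ± 0.14. The Actg2 call (adjusted p = 0.0289) was lost without saline 2, saline 4, leptin 5, leptin 6 or leptin 8 (up to 0.0860), under quantile and loess scaling (up to 0.103), without the filter (0.0643) or the mean-variance trend (0.0858), and with the actin covariate (0.399), which also ended that of Smtn (0.0883).

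Mucosal secretion genes rose on balance: of 14, 6 rose and 2 fell, and 8 rose and 2 fell adjusted over the list alone (median 0.58, camera adjusted p = 0.0017; adjusted p = 0.0645 with an estimated correlation). The trefoil factor genes Tff2 and Tff3 rose by 1.99 ± 0.19 and 0.79 ± 0.15, the immunoglobulin transporter Pigr by 0.66 ± 0.087 and Creb3l1 by 0.82 ± 0.15. Tff3 (adjusted p = 0.0663) and Creb3l1 (0.0667) lost their calls with the actin covariate, with log2 fold changes of 0.86 and 0.86 in that fit. The 2 that fell, named after their values were seen, were the mucin gene Muc3 (-0.53 ± 0.12) and the mucin glycosyltransferase gene Gcnt3 (-0.89 ± 0.23). Muc1 was at 0.028 ± 0.10 (adjusted p = 0.897), and Muc5ac was too dim to be tested. The ion and water transport list did not pass (median 0.0042, mean -0.00086, camera's direction down, adjusted p = 0.774), with 2 genes higher and 3 lower of 21, and 4 and 3 adjusted over the list alone. Carbonic anhydrase Car4 rose by 1.77 ± 0.18, and the sodium channel subunit Scnn1a changed by -1.10 ± 0.17, a call lost with the actin covariate (adjusted p = 0.0740). The other called genes, named after their values were seen, were Slc12a2 (0.71 ± 0.14), Aqp4 (-1.16 ± 0.22) and Slc4a4 (-0.35 ± 0.093). Cftr (-0.12 ± 0.24), Aqp1 (0.30 ± 0.10, adjusted p = 0.0948) and Aqp8 (0.22 ± 0.16) were not called; Aqp1 passed under quantile (0.0410) and loess scaling (0.0267).

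Bile acid and sterol transport genes did not pass as a list (19 tested, median -0.12, camera adjusted p = 0.459), with 2 higher and 1 lower, also 2 and 1 adjusted over the list alone. Abcg1, a sterol exporter, rose by 0.74 ± 0.14, as did the sterol exporter Abca1 (0.66 ± 0.14), named after its values were seen, and the drug exporter Abcb1a changed by -0.80 ± 0.14. The calls of Abcg1 and Abcb1a were lost with the actin covariate (adjusted p = 0.156 and 0.146). The sterol transporters Abcg5 (-0.25 ± 0.19) and Abcg8 (-0.040 ± 0.20), the bile acid receptor Nr1h4 (-0.36 ± 0.15) and the bile acid importer Slc10a2 (0.30 ± 0.30) were not called. With the actin covariate, Nr1h4 (-0.74, adjusted p = 0.0445), Slc10a2 (1.29, 0.0327) and the list (median -0.43, 0.0203) passed. Of 18 biliary epithelial markers, 3 fell, and 4 adjusted over the list alone (median -0.071, camera adjusted p = 0.183). The keratin genes Krt7 and Krt8 changed by -0.96 ± 0.16 and -0.58 ± 0.10, and both calls were lost with the actin covariate (adjusted p = 0.140 and 0.132). The third was Krt18 (-0.35 ± 0.089), named after its values were seen. The list passed without saline 3 (adjusted p = 0.0295). Of 19 fibroblast and matrix genes, 3 rose, and 5 rose and 1 fell adjusted over the list alone (median 0.24, camera adjusted p = 0.0053; adjusted p = 0.501 with an estimated correlation). The list's call was lost without leptin 7 (0.0646), with fry (0.110) and with the actin covariate (0.0555). Bgn, a matrix proteoglycan gene, was at 0.46 ± 0.11, a call lost without saline 1, saline 4, leptin 5 or leptin 7 (up to 0.0777), with median centring (0.0599), without the filter (0.0595) or the mean-variance trend (0.0890), and with the actin covariate (0.295). The collagen genes Col14a1 (0.69 ± 0.19) and Col6a2 (0.45 ± 0.13) lost their calls without any pool but leptin 8 (up to 0.117) and leptin 5 (up to 0.121), and with the actin covariate (0.464 and 0.0686). Both were also lost with median centring (0.0628 and 0.0775), without the filter (0.0690 and 0.0748) and without the mean-variance trend (0.0874 and 0.110), and Col14a1 with array weights (0.0751).

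Transcripts of liver cells were among the brightest in both treatments. By mean signal over the 8 arrays, Alb ranked 4, Ttr 8, Apoa2 10 and Bhmt 17 of the 45101 probe sets. Apoa1 ranked 49 and Cyp2e1 55. The labels do not say whether liver tissue was carried along with the gallbladders, so for transcripts that liver also holds, the lipid and cholesterol genes among them, the tissue they came from is not known. Albumin (Alb) had a signal of 18859 ± 454 in leptin pools and 18442 ± 2966 in saline pools (SD, n = 4), and a log2 fold change of 0.046 ± 0.11 (adjusted p = 0.836). It lay near the brightest signal of an array, 18063 to 23117, which limits the rise that its probe set can show. Of 17 hepatocyte markers 1 was called, also 1 adjusted over the list alone (median 0.021, camera adjusted p = 0.604). It was Apoa1, which rose by 0.70 ± 0.17, a call lost without saline 1, saline 4, leptin 5, leptin 6 or leptin 8 (adjusted p up to 0.0788), without the filter (0.0755) or the mean-variance trend (0.0820), and with the actin covariate (0.549). The list's median was -0.34 with the actin covariate (adjusted p = 0.0018) and 0.19 under loess scaling (0.00040).

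Other lists that did not pass were endothelial (11 tested, median 0.28, camera adjusted p = 0.0668), pancreatic acinar (6 tested, -0.22, 0.125), enterocyte (7 tested, -0.055, 0.337), ribosomal protein (17 tested, -0.073, 0.198), heat shock (13 tested, -0.092, 0.258) and endoplasmic reticulum stress (19 tested, -0.0040, 0.774). The first 3 had 1 called gene each: Cldn5 at 0.59 ± 0.16, Reg1 at -0.70 ± 0.13 and Apoa4 at -0.72 ± 0.20. Cldn5 lost its call without any pool but saline 3 (adjusted p up to 0.120), and Apoa4 without any but saline 1 and leptin 5 (up to 0.128). Both were lost under quantile and loess scaling (up to 0.0984) and without the filter or the mean-variance trend (up to 0.114), Cldn5 with median centring (0.0694), Apoa4 with a pseudocount of 1 (0.0512) and the robust variance model (0.0665), and Cldn5 (0.381) and Reg1 (0.252) with the actin covariate. The endothelial list passed without saline 3 (0.0430), leptin 6 (0.0216) or leptin 8 (0.0362) with no filter (0.0368) and with camera on ranks (0.0372), the acinar list without saline 3 (0.0456), the ribosomal list without saline 1 (0.0393) and the heat shock list without leptin 7 (0.0434). Adjusted over the list alone, these 6 lists had 1, 1, 2, 0, 3 and 3 called genes. The acinar gene Prss2 (-0.053 ± 0.33) and the enterocyte gene Fabp2 (-0.055 ± 0.24) were not called, but Fabp2 passed with the actin covariate, at -0.87 (adjusted p = 0.0408). Neural, mesothelial, erythroid and skeletal muscle lists had 4, 4, 2 and 1 tested genes, of which 0 were called, and 1, 1, 0 and 0 adjusted over the list alone.

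Of the called genes named here, 38 had other tested probe sets. In 24 of these genes all of them were called with the same sign, in 7 some were and in 7 none was (Abcb1a, Cd36, Col14a1, Col6a2, Per2, Mt1 and Cebpd); 0 had one called with the opposite sign.

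At the level of pools, the scores of 15 of the 32 tested lists did not overlap between treatments, each with the smallest p that the exact permutation test allows (p = 0.0286, adjusted 0.0610 over the 32 lists). They included 14 of the 19 lists called by camera, 8 of which rose and 11 fell. The B and plasma cell score was 1.37 ± 0.266 with leptin and -1.37 ± 0.238 with saline (SD, n = 4), and the cholesterol synthesis score -0.476 ± 0.0730 and 0.476 ± 0.118.

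**Figure D3:**
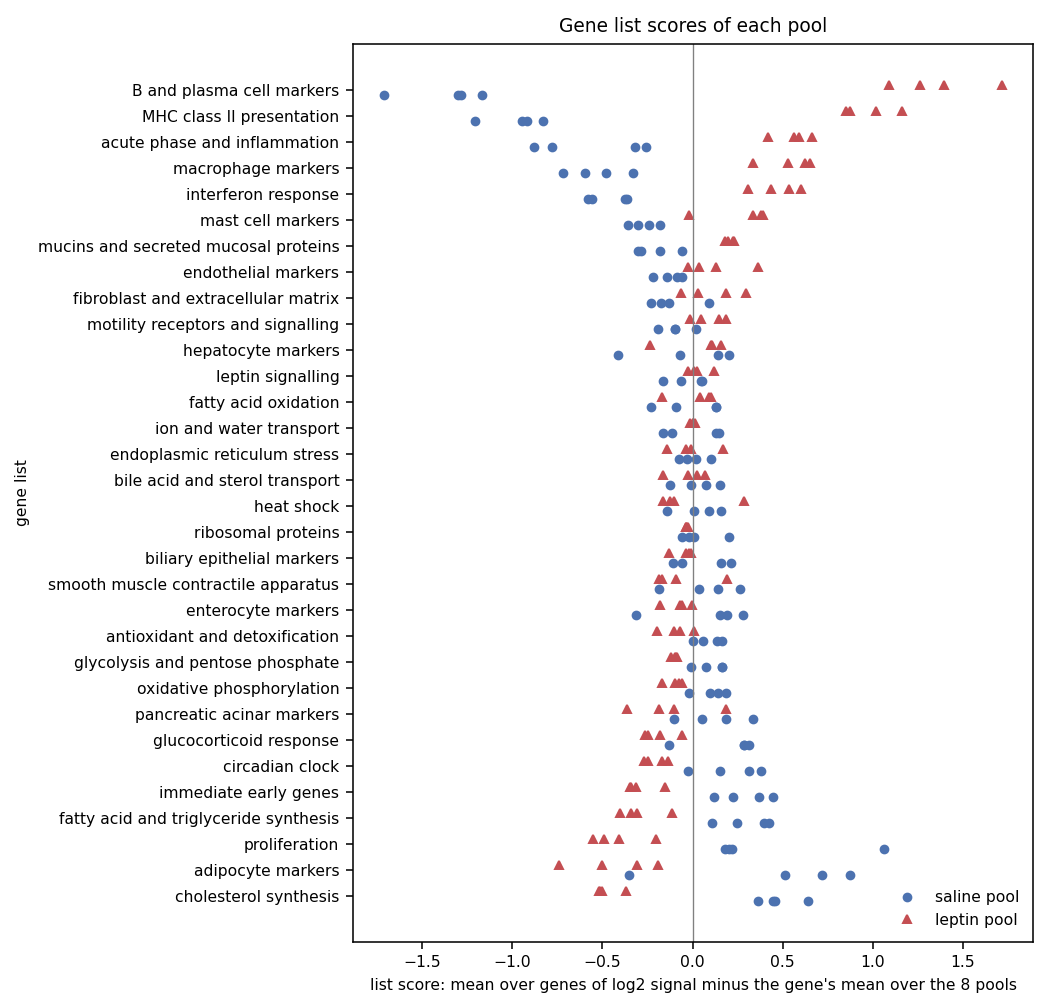
Score of each saline pool (circles) and leptin pool (triangles) for the 32 tested lists, as the mean over a list's genes of the log2 value minus the gene's mean over the 8 pools. The lists are ordered by the difference of the group means, from 2.73 for B and plasma cell markers to -0.952 for cholesterol synthesis; the hepatocyte scores of both treatments overlap.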

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

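The tests of raised background, of the scaling behind the immune genes, of a lower epithelial and muscle share, of a smaller liver share and of RNA integrity (the actin covariate) were chosen after the results were seen; the others were set earlier.

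A pool lying far from the other 3 of its treatment (Dixon's ratio above its 95% value) was seen in 23 of 380 groups of values, or 6.05%, where chance gives about 5%. In log2 signal, leptin 7 stood apart for Cxcl5 (9.63), Krt20 (7.38), Abcg8 (7.76), Ndufa4 (11.52) and Cd8a (8.82). Leptin 6 did for Chil3 (9.71), Il1rn (7.85) and Lrrn4 (8.90), leptin 5 for Car4 (9.59), Edem1 (9.01) and Rpl8 (12.51), and leptin 8 for Klrd1 (6.28). Saline 4 did for Fdps (11.29), Cidec (8.65) and Cry1 (7.93), and saline 1 for Angptl4 (10.52) and Sdhb (11.93). In list scores, leptin 6 stood apart for cholesterol synthesis (-0.37) and mast cell markers (-0.022), and leptin 7 for hepatocyte markers (-0.23) and heat shock (0.29). Saline 4 stood apart for proliferation (1.06) and glucocorticoid response (-0.13). By pool, 7 of the 23 came from leptin 7, 5 each from leptin 6 and saline 4, 3 from leptin 5, 2 from saline 1 and 1 from leptin 8.

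Chance is argued against for the count of probe sets. Of the 35 splits of the 8 pools, 1 gave as many, the real one with 1561, and the highest other gave 1. That is the smallest share that 35 splits allow. The splits also cannot tell a batch that went with treatment from the treatment. The splits cannot decide on chance for the count of gene lists called at the preset correlation. For that count, 3 of 35 splits gave at least 19, and the highest other gave 20. The others among these 3 joined saline 1 with 3 leptin pools, so they still held part of the difference between treatments. The 18 splits that mixed the treatments evenly gave 1 to 8 lists, with a median of 5.

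The dim probe sets that the filter left out were brighter on the leptin arrays, by a mean of 0.22 on the log2 scale. The tested probe sets, among which all calls lie, had a median log2 fold change of 0.039. Had such a shift between arrays made the calls, forcing 1 distribution on every array would have removed most of them. But 66.6% of the calls were made again with the same sign. Raised background on the leptin arrays cannot be told apart from more transcripts being present. The control probe sets for absent sequences differed by 0.25 ± 0.15 (SE), too imprecise to decide. No biological explanation was tested.

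Immune genes were higher in the leptin pools. The scaling between arrays is argued against by the called immune genes, of which at least 31 of 38 stayed called under each other scaling. A lower share of epithelium and muscle would raise all other cell types alike, but macrophage markers rose by 0.83 ± 0.085 (SE) more than fibroblast and endothelial markers. Lymph node tissue carried along cannot be told apart from immune cells in the gallbladder wall. B lineage genes rose by 0.58 ± 0.10 (SE) more than T cell and lymph node genes, past the bound set beforehand. But that bound presumed equal baselines. The 12 T cell and lymph node genes also rose, by a mean of 0.74, though unevenly, from -0.24 for Themis to 3.27 for Ltb. In the leptin pools 4 of the 12 had a mean signal under background. An effect of the leptin treatment itself on the immune genes was not tested and stays open.

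Cholesterol synthesis genes were lower in the leptin pools, by a mean of -0.95. RNA integrity as the whole cause is argued against by a mean change of -0.91 ± 0.11 (SE) with the actin ratio as covariate. A smaller share of liver cells as the whole cause is argued against too, since hepatocyte markers lay 1.02 ± 0.18 (SE) above the list. So did Ahsg, Cps1 and Tat alone, the 3 markers far below the top of the arrays' range, by 1.10 ± 0.25 (SE). The hepatocyte median varied with the fit: -0.34 with the actin covariate (camera adjusted p = 0.0018) and 0.19 under loess scaling (0.00040). A smaller liver share as part of the cause therefore stays open. With the adipocyte score as covariate the mean change was -1.12 ± 0.067 (SE), but this cannot decide on fewer adipocytes, which stay open. That fit rests on differences between pools of the same treatment. These came chiefly from saline 4 (adipocyte score -0.35, cholesterol score 0.64) and leptin 6 (-0.74 and -0.37). A change inside liver cells and an effect of the leptin treatment on the gallbladder's own cells were not tested and stay open.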

How the results depend on the processing

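The actin covariate was chosen after the data were seen; all other alternatives were set earlier. The count of probe sets (1561) stayed within 1.5 times under every scaling, pseudocount, filter, variance model and weighting tried, from 1080 without the mean-variance trend to 2112 with array weights. It was 654 with the actin covariate, which kept 379 of the 1561 calls, and 2763 at an adjusted p of 0.10. With 1 pool left out it ranged from 884 to 1431, where fewer arrays are part of the cause. The count of lists (19) ranged from 14 to 21, and was 18 to 21 with 1 pool left out, but was 4 with an estimated correlation. A result counted as reversed only when its direction changed and it was called in the main fit or the alternative. Changes of direction in uncalled results were not counted. Of list results, 1 reversed in this sense: the hepatocyte median was -0.34 with the actin covariate. The cause was not tested. Over all alternatives, 0 of 2959 values of named genes reversed in the same sense, 235 lost their call and 66 gained one. Of the 94 called named genes, 73 kept their call under each scaling and without each pool, and 53 with the actin covariate. Dim probe sets, near the background signal of 46.0, limit what could be tested: without the filter the median log2 fold change of all probe sets was 0.12. No paired analysis was possible because the treatments share no replicate number.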

Other observations

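The 4 gene groups here and their tests were chosen after the values were seen, so their tests are no independent evidence.

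Of 14 tested genes of alternatively activated macrophages, 8 rose, with a median of 1.01 (camera adjusted p = 1.3e-11 over these 4 groups, and adjusted p = 0.0066 with an estimated correlation). The chemokine gene Ccl8 rose by 2.83 ± 0.18 (SE) and the lectin gene Mgl2 by 0.98 ± 0.21, while Arg1, another gene used as a marker of this state and also a liver enzyme, was at 0.069 ± 0.19 and not called. Of 10 neutrophil genes, 6 rose, with a median of 1.42 (camera adjusted p = 8.3e-10, and adjusted p = 0.0306 with an estimated correlation). S100a9 rose by 2.87 ± 0.24, Csf3r by 1.78 ± 0.26 and Pglyrp1 by 1.27 ± 0.24, while the granule gene Ngp was at 0.00078 ± 0.22. Mmp9 (0.91 ± 0.27), Fpr2 (0.64 ± 0.39) and Mmp8 (0.48 ± 0.27) were not called either. The first group's 8 include Chil4, Chil3 and Retnla, described above, and Mrc1 of the macrophage list. The second group's 6 include S100a8, Ltf and Lcn2, described above, so the counts and tests of both groups rest partly on genes already given.

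Genes for the assembly of ribosomes fell in 9 of 26 cases, with a median of -0.48 (camera adjusted p = 5.5e-10; adjusted p = 0.0504 with an estimated correlation). Nop58 changed by -1.31 ± 0.16, Nolc1 by -0.86 ± 0.18 and Ncl by -0.47 ± 0.096, whereas 0 of the 17 tested ribosomal protein genes were called. Of 38 genes for liver enzymes and secreted proteins, 9 rose and 8 fell (median 0.048, camera adjusted p = 0.521). Whether liver tissue was carried along with the gallbladders is not said in the labels, so these values are not known to be those of gallbladder cells. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.38 ± 0.22, Elovl2 by 1.79 ± 0.24 and Mup3 by 1.63 ± 0.27. Gsta2 changed by -1.29 ± 0.16, Cyp2d9 by -1.20 ± 0.23 and Khk, the first enzyme of fructose use, by -0.89 ± 0.19.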
